A study of Nezara viridula with 24 samples.

How the data were processed

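RNA was measured in adults of the southern green stink bug, Nezara viridula, a plant-feeding insect that pierces its food and digests it in saliva and along a sectioned midgut. The labels describe 8 groups of 3 libraries, made from salivary glands and from midgut sections M1, M2 and M3 of insects given corn or green bean. Insects fed for 24 h after the adult moult, and each library pooled the tissue of 4 to 10 individuals. The labels number the replicates from 1 to 3 in each group. Nothing in them says whether the pools came from separate cultures, so p-values measure only the spread between these pools.

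The deposited tables hold estimated counts, as whole numbers, for 298322 transcripts of a Trinity assembly, a set of transcripts built from the reads themselves, which fall into 201329 Trinity genes. Per the submitters' processing notes, Trim Galore 0.4.4, Salmon 0.12 and DESeq2 1.20.0 were used, with no role or order given. There were 3 tables, one of 12 libraries from corn-fed insects, one of 6 gland libraries and one of 18 midgut libraries, so every corn library stands in a pair of tables. The same library differed between its tables by a factor that belonged to the transcript and not to the library. For the 3 shared gland libraries, the factor had a standard deviation of 0.0478 on the log2 scale over 1071 transcripts with at least 1000 counts, and the residual around it was 0.00141. The midgut and corn tables shared 9 libraries, with a factor of standard deviation 0.0146 and a residual of 0.0024 over 1160 transcripts. Library totals differed by at most 0.0274% between tables. Estimated counts that were rescaled within each table by an average transcript length would behave in this way, but how the tables were made is not given in the sources used here. Each test therefore stayed within one table, and every level quoted belongs to the table of its comparison.

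The 3 tables used here do not pair transcripts with gene names or descriptions, and no annotation was used. Gene lists fixed before the data were examined, covering digestive enzymes, detoxification, transport, salivary proteins, tissue markers and plant, bacterial or viral products, could not be applied, and transcripts appear under their assembly identifiers. In such an identifier, the ending that starts with i marks the isoform of a Trinity gene. Isoforms of one Trinity gene can share reads, and the quantifier's division of shared reads among them is uncertain. The rule for named transcripts, also fixed before the data were examined, took per comparison the 2 with the largest rise and the 2 with the largest fall. Candidates needed an adjusted p under 0.05, an absolute log2 fold change of at least 1, no overlap between the groups' values and a mean of at least 10 CPM (a count relative to the TMM-scaled total of its library) in the higher group.

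Counts were analysed in R 4.3.3 with edgeR 4.0.16. Transcripts were kept by filterByExpr with the groups as classes, which left 37229 in the corn table, 45390 in the midgut table and 23969 in the gland table, holding 99.3%, 99.2% and 99.1% of the counts. Libraries were scaled by the trimmed mean of M-values (TMM). A model with a mean per group was fitted to all libraries of the table with glmQLFit (robust, trended dispersion), since 3 libraries give little information on the spread alone, and contrasts were tested two-sided with glmQLFTest. Adjusted p-values are Benjamini-Hochberg values over the transcripts of the table. A standard error of a log2 fold change is its size divided by the square root of the F statistic. Levels are TMM-scaled CPM, as mean ± standard deviation over libraries. Folds of named transcripts are ratios of counts summed over each group, on the CPM scale. Fitted log2 fold changes average the groups of a contrast on the log scale and so differ from these ratios. They are not given for named transcripts where a tissue and diet group of the contrast was at 0 in all 3 libraries, since they then depend on the prior count, except for fits without a library, where this is said. Where every library of one side was at 0, the fold is a lower bound by convention, set against 3 counts over that side. Intervals of folds are 95% exact binomial intervals and cover counting error only. Lower ends of such intervals lie below the conventional bounds, at 16630 against 20450 for TRINITY_DN783_c0_g1_i16. Neither covers the spread between pools.

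Library totals ran from 17819164 to 33954593 counts, so 3 counts correspond to well under 1 CPM. Every column of the tables was matched to a labelled library, and no library was left out of the fits that carry the results. The 24 pairs of replicates differed by 56.5 to 297 times the sampling noise (chi-square per degree of freedom over transcripts with at least 20 joint counts), so none appeared to be a library deposited in duplicate.

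Replicate numbers are shared between groups, and whether they pair the samples was examined by correlating deviations from group means between same-numbered libraries. Between salivary glands and the mean of the midgut sections on corn, the correlations were 0.421, 0.158 and 0.22, all above the limit of 0.1 set beforehand, so the numbers were taken as pairs there, from the data and not from the labels. The highest correlation with another number was 0.143 for replicate 2 and 0.0868 for replicate 3. A difference of replicate 1 from the other numbers that all tissues share would also raise these correlations, so pairing of replicates 2 and 3 is weakly shown. In the other comparisons at least 1 pair lay below 0.1. The model without a block carries the results throughout.

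The tissue specificity index tau was computed over the 4 tissue means of log2(CPM + 1) on corn. A transcript counted as restricted when tau was at least 0.8 and its highest tissue mean at least 1 CPM.

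The fits were tested on simulated counts with 200 transcripts changed by known folds. Counts were drawn from the real library sizes, a single mean per transcript over all groups and the dispersion trend. The changed transcripts had a mean of at least 1 CPM. Spread beyond the trend, groups at 0 and systematic differences between libraries of a group were not simulated. The shares below may therefore not hold for the real counts. For salivary glands against midgut, over 32835 simulated transcripts, 0% of the changed transcripts were called at 2-fold, 13.4% at 4-fold and 66.7% at 16-fold, and 0 of 53 calls were false. For M3 against M1, over 42033 transcripts, the shares were 0%, 16.4% and 72.7%, with 1 false call in 60. For diet in M1, over 42635 transcripts, they were 0%, 1.49% and 28.8%, with 1 false call in 21. For diet in salivary glands, over 21423 transcripts, they were 0%, 13.6% and 71.2%, with 4 false calls in 55.

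The alternatives were no filter on low counts, a replicate block, each library left out in turn, DESeq2 size factors inside edgeR, the DESeq2 1.42.0 test, a minimum fold change or a stricter adjusted p, counts summed per Trinity gene, fits to one diet, section or table, and other settings of tau. The planned fits with 1 library left out were filtered anew, which lets more transcripts through. Fits with 1 library left out but the transcripts of the full fit, fits without libraries that stood apart, and a block within each diet were chosen after seeing the data.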

Results

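Transcript abundance was measured by RNA sequencing in 24 libraries from adult Nezara viridula, the southern green stink bug. Salivary glands and midgut sections M1, M2 and M3 were dissected from insects given corn or green bean for 24 h, and each of the 8 combinations of tissue and diet is represented by 3 libraries, each a pool of 4 to 10 individuals. Library totals lay between 17819164 and 33954593 estimated counts. The design allows the salivary glands to be set against the midgut, the midgut sections against one another, and the diets against each other within each tissue.

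Counts were concentrated in few transcripts, by group mean most of all in the salivary glands. In corn glands, 70 ± 6.25 transcripts (SD, n = 3) held 50% of the counts, and in green bean glands 47 ± 7.94. In the midgut the corresponding number ranged from 106 ± 71.8 transcripts in corn M2 to 206 ± 71.5 in corn M3. The lowest corn M2 library, at 47, lay within the range of the glands. TRINITY_DN223_c10_g2_i1 had the largest count in all 18 midgut libraries and in 3 of 6 gland libraries. It took 9.15% ± 0.415 of the counts in green bean M1, 17.9% ± 2.88 in corn M2 and 6.08% ± 1.58 in corn glands (SD, n = 3 each), and it passed the edgeR test in none of the 8 pairwise comparisons (lowest adjusted p = 0.2376, for diet in M2). It was singled out after its values were seen.

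The number of transcripts with at least 1 count separated libraries of one diet. Corn replicate 1 detected 109035 to 166312 transcripts over the 4 tissues, green bean libraries 89662 to 131963, and corn replicates 2 and 3 detected 53451 to 87057, although their totals lay inside the range of the green bean libraries. This division is not named in the labels. It is given here because each comparison of diets sets it partly against the diet.

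**Figure D1:**
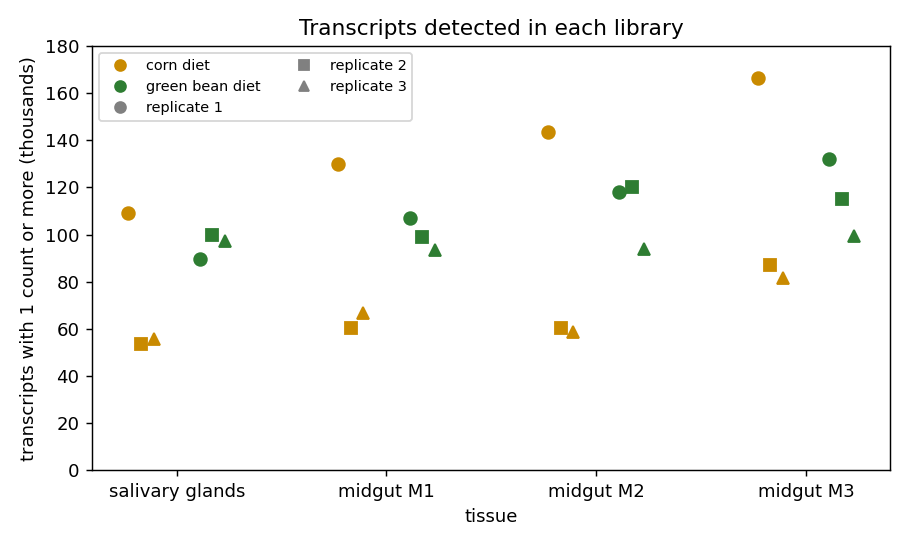
Transcripts with at least 1 count (vertical axis, in units of 1000) in each of the 24 libraries, by tissue, diet (colour) and replicate number (marker). In every tissue corn replicates 2 and 3 lie lowest and corn replicate 1 highest.

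The first principal component of the corn table, 43.2% of the variance of log2 CPM, separated the 3 gland libraries from the 9 midgut libraries. In the midgut table the first component (20.5%) placed all 6 libraries of corn replicates 2 and 3 below the other 12, and the other one shown ran from M1 to M3.

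**Figure D2:**
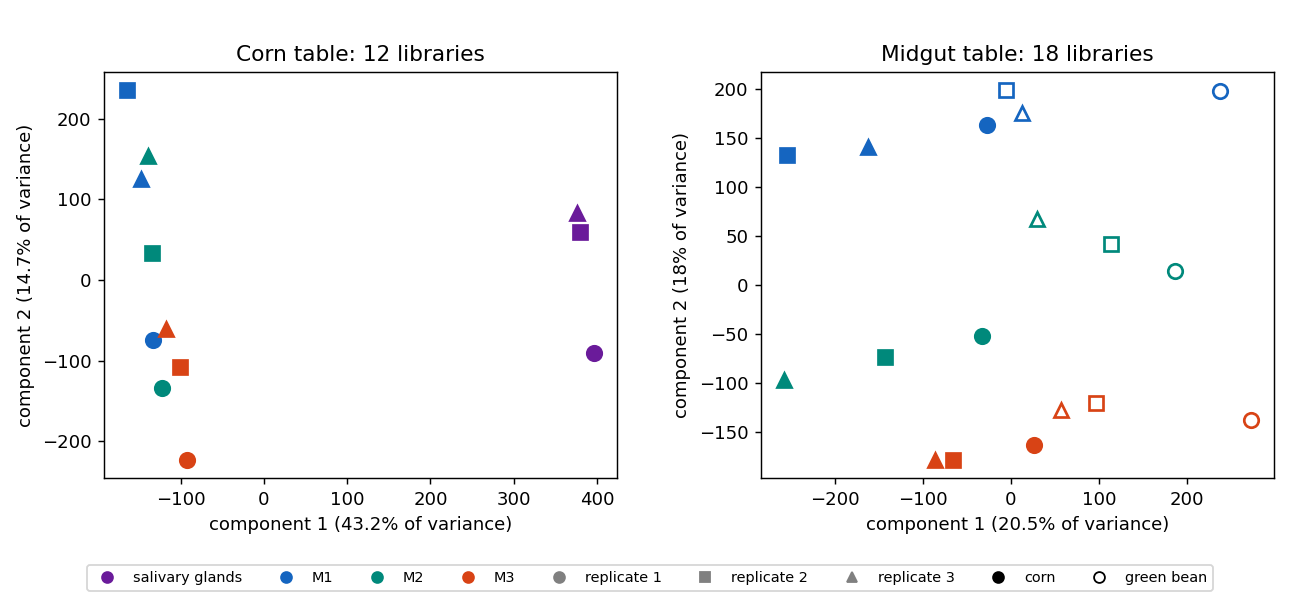
First and second principal components (axes in log2 CPM units, with the percent of variance) of the 12 corn libraries and of the 18 midgut libraries. Colour gives the tissue, marker the replicate number, and filled or open symbols the diet. Glands stand apart from midgut on component 1 on the left, and M1 lies above M3 on component 2 on the right.

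Salivary glands were compared with the mean of the 3 midgut sections on corn, to find which transcripts distinguish the tissue that makes saliva from the tissue that digests and absorbs. The 4125 transcripts that were higher in the glands held 71.4% ± 1.57 of gland counts, against 3.74% ± 0.633 in M1, 3.47% ± 0.605 in M2 and 4.19% ± 0.252 in M3 (SD, n = 3 each). The 5113 that were lower held 2.01% ± 0.0315 of gland counts, and 54.3% ± 3.53, 44.9% ± 2.53 and 42.9% ± 1.92 of the counts in M1, M2 and M3. TRINITY_DN2_c4_g1_i7 averaged 1119 ± 562 CPM in glands (n = 3) and 0.0313 ± 0.094 CPM in midgut (n = 9), a ratio of 47100 with a counting interval from 21640 to 128400 (edgeR adjusted p = 5.7352e-05). All 6 of its midgut counts lay in corn M2 replicate 3. TRINITY_DN1916_c0_g1_i5 averaged 2920.5 ± 892 CPM in glands and 0.571 ± 0.976 in midgut, a ratio of 7242 (5965 to 8882, edgeR adjusted p = 2.1714e-06). In the other direction, TRINITY_DN783_c0_g1_i16 had no count in any gland library and 1404 ± 299.7 CPM in midgut, at least 20450-fold lower in glands (edgeR adjusted p = 2.5407e-07). TRINITY_DN15724_c0_g1_i3, also without a gland count, averaged 268 ± 106 CPM in midgut and was at least 3650-fold lower in glands (edgeR adjusted p = 6.4464e-07). In total, edgeR's quasi-likelihood test called 9238 of 37229 transcripts, and the median log2 fold change of all tested transcripts was -0.17. With no filter on low counts the balance of directions turned around, with 8333 transcripts higher and 4908 lower in glands. DESeq2 size factors shift all of these fold changes by 0.116 on the log2 scale, far less than the changes named. Of the calls, 7334 had no overlap between gland and midgut libraries. Among the 1740 Trinity genes with at least 2 called isoforms, 255 had isoforms called in both directions.

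**Figure D3:**
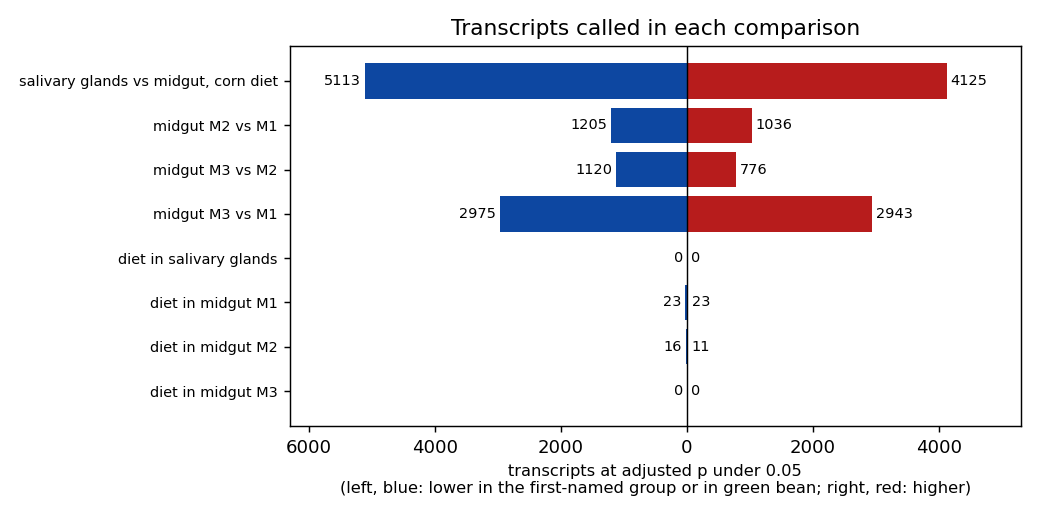
Number of transcripts called at an edgeR adjusted p under 0.05 (horizontal axis), lower in the first-named group or on green bean to the left (blue) and higher to the right (red), in 8 pairwise comparisons. The tissue comparisons call between 1896 and 9238 transcripts, the diet comparisons at most 46.

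How many transcripts are largely restricted to one tissue was described with the index tau on corn. Of 27436 transcripts with a tissue mean of at least 1 CPM, 4433 (16.2%) had a tau of at least 0.8. Of these, 2615 were highest in salivary glands, 981 in M1, 238 in M2 and 599 in M3. A transcript at like levels in all 3 midgut sections cannot reach this tau, even when glands lack it. Glands were not sectioned, so the number for glands and those for the sections do not compare like with like. These numbers depend on the cut-off, with 2027, 557, 102 and 251 at a tau of at least 0.9, and 1979, 576, 114 and 338 with a pseudocount of 0.1. Without the level of 1 CPM, the only filter here, 251288 transcripts entered, most of them below that level, and M3 held the largest number with such a tau, 35915, against 28419 in salivary glands, 23123 in M1 and 21686 in M2. Those are not restricted transcripts as defined above. The gland set held 42.2% ± 1.02 of gland counts and 0.0708% ± 0.0148 of M3 counts, the midgut section where it was highest (SD, n = 3). The M1 set held 3.42% ± 0.384 of M1 counts, the M2 set 0.267% ± 0.0721 of M2 counts and the M3 set 0.437% ± 0.106 of M3 counts. In the green bean libraries, which had no part in defining the sets, the gland set held 44.3% ± 1.8 of gland counts and the M1 set 3.29% ± 0.257 of M1 counts. The M1 set took 0.285% ± 0.152 in green bean M2 against 0.0579% ± 0.0055 in corn M2. The sets were chosen for low corn levels outside their tissue, so a higher share on green bean can come from the choice alone. All sets had higher shares on green bean in every tissue other than their own, and none of these differences was tested.

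Sections of the midgut were compared over both diets, 6 libraries against 6. Between the first and second section, TRINITY_DN256_c0_g1_i3 had no count in any M1 library and 341 ± 328 CPM in M2, at least 15730-fold higher (edgeR adjusted p = 4.3317e-05). Another isoform of the same Trinity gene, TRINITY_DN256_c0_g1_i7, averaged 6940 ± 4945 CPM in M2 and 1.13 ± 2.46 in M1, a ratio of 7804 (log2 fold change 13.72, SE 1.30, edgeR adjusted p = 2.1004e-05). Its size depends on single libraries, since 83 of its 102 M1 counts lay in corn M1 replicate 2 and those of green bean M1, 8 in number, in replicate 3. With the transcripts of the full fit, a setting chosen after seeing the data, the log2 fold change was 15.33 without the first of these libraries and 15.95 without the other, which leaves green bean M1 at 0 and the value to the prior count. TRINITY_DN3388_c0_g1_i3 fell from 214 ± 87.8 CPM in M1 to 0.359 ± 0.879 in M2, a ratio of 694.1 (515.1 to 959.3, edgeR adjusted p = 0.0027322), and TRINITY_DN514_c0_g2_i14 from 44.1 ± 46 to 0.0323 ± 0.0792 CPM, a ratio of 1144 (489.8 to 3524, edgeR adjusted p = 0.0036216). Both ratios rest on single libraries, since all 43 M2 counts of TRINITY_DN3388_c0_g1_i3 lay in corn M2 replicate 2 and all 5 of TRINITY_DN514_c0_g2_i14 in green bean M2 replicate 3, and without these libraries M2 was at 0. TRINITY_DN3388_c0_g1_i3 did not pass with no filter on low counts (adjusted p = 0.09607) or in corn libraries alone (0.1043, and 0.1071 in the corn table), and TRINITY_DN514_c0_g2_i14 passed neither in corn (0.09857) nor in green bean libraries alone (0.09257). In a fit chosen after seeing the data, without corn replicates 2 and 3, TRINITY_DN514_c0_g2_i14 and TRINITY_DN256_c0_g1_i3 did not pass (0.1746 and 0.06949). In all, 1036 transcripts were higher and 1205 lower in M2 than in M1. Fits to one diet gave 271 higher and 429 lower in corn libraries alone and 343 higher and 172 lower in green bean libraries alone. Whether the diets differ in this balance was not tested. Among transcripts kept on both diets, 95.51% of the higher and 98.81% of the lower corn calls had the same sign on green bean. The 1205 held 26.8% ± 2.51 of counts in corn M1 and 22.8% ± 0.235 in green bean M1, against 2.37% ± 0.216 and 3.7% ± 1.38 in M2. With 1 library left out the count of 2241 became 1311 to 1867, but those fits were filtered anew and tested 50938 to 60489 transcripts. With the 45390 transcripts of the full fit it was 1614 to 2110. DESeq2 called 4367.

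Between M2 and M3, TRINITY_DN396_c0_g2_i3 rose from 0.0417 ± 0.102 CPM in M2 to 32.5 ± 21.7 in M3, a ratio of 975.9 (417.9 to 3007, edgeR adjusted p = 0.001927). TRINITY_DN396_c0_g2_i1, an isoform of the same Trinity gene, rose from 0.0248 ± 0.0608 to 16.4 ± 8.48 CPM, a ratio of 623.3 (243.2 to 2289, edgeR adjusted p = 0.00021544). Their M2 counts, 5 and 4, lay in corn M2 replicate 2 and corn M2 replicate 1 alone. TRINITY_DN926_c0_g1_i10 averaged 228 ± 82.1 CPM in M2 and had no count in any of the 6 M3 libraries, at least 14460-fold lower (edgeR adjusted p = 7.483e-07). TRINITY_DN3036_c0_g1_i2 fell from 290.4 ± 200.5 CPM in M2 to 0.155 ± 0.379 in M3, a ratio of 2097 (1409 to 3273, edgeR adjusted p = 0.0077271), where all 24 M3 counts lay in corn M3 replicate 2. TRINITY_DN3036_c0_g1_i2 did not pass with no filter on low counts (adjusted p = 0.1356), in corn libraries alone (0.1318, and 0.1363 in the corn table), in green bean libraries alone (0.1442), or, in fits chosen after seeing the data, without corn replicate 1 (0.05494) or without corn replicates 2 and 3 (0.2873). TRINITY_DN396_c0_g2_i3 did not pass in corn (0.06863, and 0.07651 in the corn table) or green bean libraries alone (0.07895), and without corn replicates 2 and 3 neither isoform of that gene passed (0.1189 and 0.08104). The test called 776 transcripts higher and 1120 lower in M3. The 776 held 6.77% ± 0.485 of counts in corn M3 and 6.75% ± 0.835 in green bean M3, against 2.04% ± 0.315 and 1.42% ± 0.0944 in M2. Leaving out 1 library changed the count of 1896 to 1102 to 1459 among 50971 to 60461 transcripts filtered anew, and 1376 to 1818 with the 45390 of the full fit. DESeq2 called 4336.

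M1 and M3 differed most among the sections. TRINITY_DN256_c0_g1_i3 was at 448 ± 132 CPM in M3 and at 0 in all 6 M1 libraries, at least 18710-fold higher in M3 (edgeR adjusted p = 1.3088e-05), and TRINITY_DN256_c0_g1_i7 reached 17695 ± 6821 CPM in M3 against 1.13 ± 2.46 in M1, a ratio of 21510 (log2 fold change 15.16, SE 1.35, edgeR adjusted p = 3.43e-06, with 16.77 without corn M1 replicate 2 and 17.39 without green bean M1 replicate 3, as in the comparison with M2). TRINITY_DN3388_c0_g1_i3, at 214 ± 87.8 CPM in M1, had no count in M3 and was at least 12370-fold lower there (edgeR adjusted p = 0.00061864). TRINITY_DN926_c0_g1_i10, at 183 ± 59.4 CPM in M1, was also at 0 in M3, at least 11140-fold lower (edgeR adjusted p = 7.0522e-08). Of 45390 transcripts tested, 2943 were higher and 2975 lower in M3 than in M1. The lower set held 41.5% ± 3.66 of counts in corn M1, 13.7% ± 0.0922 in corn M2 and 7.69% ± 0.723 in corn M3, and 37.6% ± 1.46, 17.8% ± 1.84 and 8.14% ± 0.27 in the green bean sections (SD, n = 3 each). The mean of M2 lay between those of M1 and M3 for 2407 (81.8%) of the higher transcripts and 2436 (81.9%) of the lower ones. These transcripts were chosen for their difference between M1 and M3, which by itself makes a mean of M2 between them more common, so the shares are no test of a gradient. Over all tested transcripts, not chosen for a difference between M1 and M3, the share was 44.2%, which is no reference value for the chosen ones. The 3 section comparisons share libraries, so their counts are not independent.

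**Figure D4:**
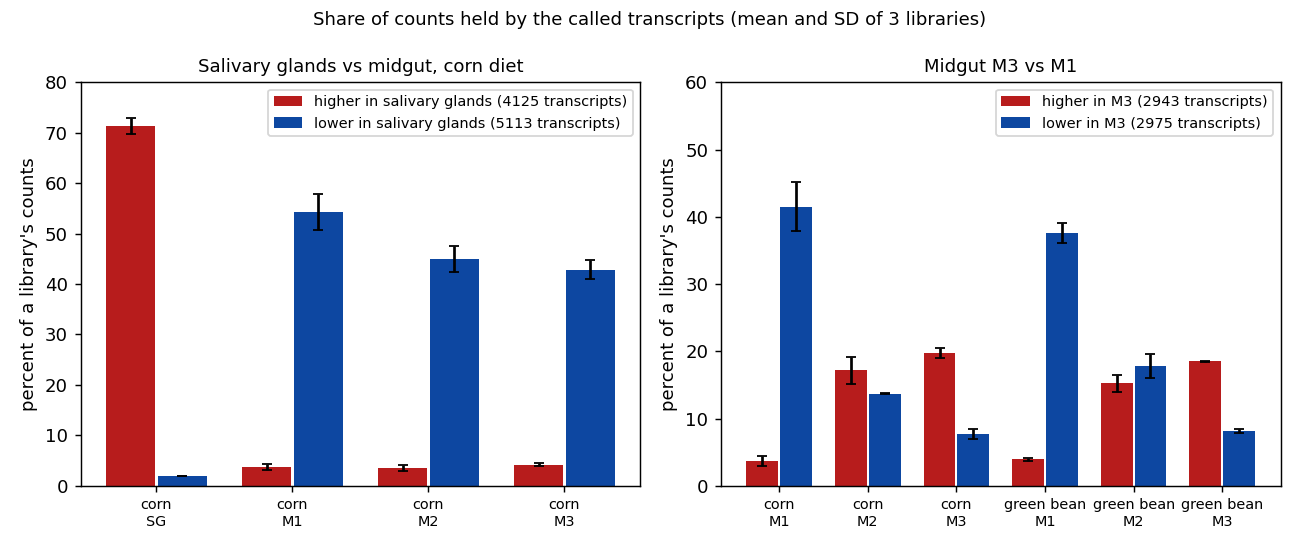
Percent of a library's counts (vertical axis) held by the transcripts called higher or lower in salivary glands than in midgut (left) and in M3 than in M1 (right). Bars are means and error bars SDs of 3 libraries. The transcripts higher in glands hold 71.4% of gland counts and at most 4.19% of midgut counts, and the share of those lower in M3 falls from M1 through M2 to M3 on both diets. All sets were called from the libraries shown, those on the right from both diets together. The differences between glands and midgut and between M1 and M3 therefore come with the choice.

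Section differences were also fitted apart in the diets, which share no libraries, over 30280 transcripts kept in both. For M3 against M1, 512 transcripts were called higher on corn and 1239 on green bean, with 321 in both, where independent lists of these sizes would share 20.95. The lower calls numbered 998 and 1232, with 663 in both and 40.61 for independent lists. Of the corn calls, 99.2% of the higher and 99.1% of the lower ones had the same sign on green bean. The same held for M3 against M2, with 156 lower calls on corn, 506 on green bean, 101 in both and 2.607 for independent lists.

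Diet was compared within each tissue, 3 green bean against 3 corn libraries, to find which transcripts respond to the food plant. In M1, TRINITY_DN870_c0_g1_i3 averaged 59.1 ± 22.8 CPM on green bean and had no count on corn, at least 1140-fold higher (edgeR adjusted p = 0.0080128), and TRINITY_DN6183_c1_g2_i4 averaged 20.1 ± 6.06 CPM on green bean and 0 on corn, at least 393.6-fold higher (edgeR adjusted p = 0.010806). Over the 12 libraries of each diet, the other isoforms of TRINITY_DN870_c0_g1 stood at 175.4 ± 62.1 CPM on green bean and 173.8 ± 72.4 on corn. Those of TRINITY_DN6183_c1_g2 stood at 27.4 ± 13.8 and 29.3 ± 27.2 CPM. Both transcripts, here and in M2, are therefore isoforms of genes whose other isoforms, over all tissues together, were present on both diets. A second isoform of the first gene, TRINITY_DN870_c0_g1_i2, is not among those other isoforms. It too was called higher on green bean without a count on corn, in M1 (edgeR adjusted p = 0.028778) and in M2 (0.041011). TRINITY_DN1041_c0_g1_i1 had no count on green bean and 17.3 ± 10.5 CPM on corn, at least 342.9-fold lower on green bean (edgeR adjusted p = 0.028778), and TRINITY_DN52_c0_g1_i13 had none on green bean and 12.1 ± 6.55 CPM on corn, at least 306.6-fold lower (edgeR adjusted p = 0.0080128). TRINITY_DN1041_c0_g1_i1 no longer passed without any 1 of the 3 green bean M1 libraries or without corn M1 replicate 2 or 3 (adjusted p 0.0872 to 0.1108, and 0.07221 to 0.09388 with the transcripts of the full fit) or with a replicate block (0.05238), and TRINITY_DN6183_c1_g2_i4 no longer passed without corn M1 replicate 2 (adjusted p = 0.05727, but 0.0474 with the transcripts of the full fit). Without corn replicates 2 and 3, a fit chosen after seeing the data, TRINITY_DN870_c0_g1_i3, TRINITY_DN1041_c0_g1_i1 and TRINITY_DN52_c0_g1_i13 did not pass (0.1079, 0.2389 and 0.06235), although the remaining corn library had 0, 5.97 and 17.8 CPM of them, so that their calls were lost and not their differences. Fitted to the 6 libraries of M1 alone, none of the 4 named transcripts passed with edgeR (adjusted p 0.1593, 0.1593, 0.2282 and 0.2282 in the order named), and that fit called 1 transcript, with 1873 at an unadjusted p under 0.05. The test called 46 transcripts, 23 higher and 23 lower on green bean, all without overlap between the diets, which 13.3% of all tested transcripts also showed and chance gives for 10%. With 1 library left out the count was 15 to 73, and with the transcripts of the full fit 17 to 98, lowest without corn M1 replicate 2 and highest without corn M1 replicate 1. The 23 higher transcripts held 2.89% ± 1.73 of counts in green bean M1, 0.0234% ± 0.0103 in corn M1 and at most 0.165% ± 0.0831 in the other green bean sections. Of these, 7 were isoforms of a single Trinity gene. Summed over its isoforms, this gene averaged 30460 ± 18770 CPM in green bean M1 and 571 ± 276 in corn M1 (log2 fold change 5.74, SE 0.86, edgeR adjusted p = 0.0454 over 23008 Trinity genes), higher in each of 3 libraries than in any of the 3 corn libraries. Corn M1 libraries lay at 280.7 to 830.1 CPM of it and green bean M1 libraries at 10840 or more. Without corn replicates 2 and 3 this gene thus lost its call and not its difference. In M2 it averaged 1486 ± 832 and 469.6 ± 270.0 CPM and did not pass the test (edgeR adjusted p = 0.233), and the difference of its diet effect between sections did not pass either (edgeR adjusted p = 0.952). It was singled out after its values were seen.

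In M2, TRINITY_DN870_c0_g1_i3 averaged 55.5 ± 40.2 CPM on green bean with no count on corn, at least 1209-fold higher (edgeR adjusted p = 0.036789). TRINITY_DN6183_c1_g2_i4 averaged 15 ± 2.56 CPM on green bean and 0.062 ± 0.107 on corn (log2 fold change 7.65, SE 1.03, edgeR adjusted p = 0.041011). Its 5 corn counts all lay in corn M2 replicate 1, and without that library the log2 fold change was 11.61 (transcripts of the full fit), a value that depends on the prior count since corn M2 is then at 0. TRINITY_DN1041_c0_g1_i1 had no count on green bean and 11.3 ± 9.37 CPM on corn, at least 285.3-fold lower (edgeR adjusted p = 0.043342). TRINITY_DN36618_c0_g1_i1 averaged 0.0664 ± 0.0272 CPM on green bean and 277 ± 291 on corn, where its lowest library was at 0.223 and its highest at 579.6 (log2 fold change -11.90, SE 1.94, edgeR adjusted p = 0.043342). In M3 this transcript stood at 151.3, 240.65 and 342.95 CPM in corn replicates 1, 2 and 3. Green bean M3 libraries had at most 0.0753 CPM of it, though no transcript passed there. Its log2 fold change in M2 was -1.50 with corn replicate 1 as the only corn library, a fit chosen after seeing the data. Its size in M2 therefore comes from corn replicates 2 and 3. TRINITY_DN870_c0_g1_i3 lost only its call in that fit, as the remaining corn library was at 0 like the others. TRINITY_DN1041_c0_g1_i1 did not pass and stood at 1.34 CPM in that library, still above green bean. With a replicate block TRINITY_DN6183_c1_g2_i4 (adjusted p = 0.06615), TRINITY_DN1041_c0_g1_i1 (0.0701) and TRINITY_DN36618_c0_g1_i1 (0.07332) did not pass. Fitted to the 6 libraries of M2 alone, no transcript passed with edgeR (3418 at an unadjusted p under 0.05), with adjusted p of 0.1348 for TRINITY_DN870_c0_g1_i3, 0.1506 for TRINITY_DN6183_c1_g2_i4 and 0.1727 for TRINITY_DN1041_c0_g1_i1, while TRINITY_DN36618_c0_g1_i1 was not tested. In all, 27 transcripts passed, 11 higher and 16 lower on green bean. The count was 162 without corn M2 replicate 1, and 0 or 1 with edgeR (3967 to 5648 at an unadjusted p under 0.05) without any of the other 5 libraries, green bean M2 replicates 1, 2 and 3 and corn M2 replicates 2 and 3. With the transcripts of the full fit it was 415 without corn M2 replicate 1 and 0 to 4 without any of the others (3902 to 5533 at an unadjusted p under 0.05). Without corn M2 replicate 1, 25 of the 27 were still called, among them all 4 named transcripts (adjusted p 6.738e-05 to 0.0229). TRINITY_DN870_c0_g1_i3 lost its call without any 1 of the other 5 libraries except green bean M2 replicate 3, and the other 3 named transcripts lost theirs without any 1 of the 5, also with the transcripts of the full fit, all in the same direction.

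No transcript passed for diet in M3 or in salivary glands with edgeR. At an unadjusted p under 0.05 there were 3236 of 45390 transcripts in M3 and 1575 of 23969 in the glands, against the 5% that chance gives. These zeros depend on the settings. DESeq2 called 1280 in M3 and 650 in the glands, as well as 1954 in M1 and 3673 in M2. With no filter on low counts edgeR called 2362 in M3 and 980 in the glands. The 6 libraries of M3 alone gave 3, a replicate block 1 in M3, sums per Trinity gene 15 in the glands, and the glands without green bean replicate 3 gave 1.

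The division among the corn libraries bears on all of these diet counts. In fits chosen after seeing the data, with replicate 1 left out of every corn group, 254 transcripts passed in M1, 1722 in M2, 6 in M3 and 0 in the glands (3393 at an unadjusted p under 0.05, with edgeR). With counts summed per Trinity gene, those fits called 1043 genes in M1, 3830 in M2, 3 in M3 and 78 in the glands. With corn replicate 1 as the only corn library, 31, 90 and 44 transcripts passed in M1, M2 and M3, 29, 89 and 42 of them higher on green bean, and with sums per Trinity gene 0, 1 and 0 passed with edgeR (2250, 4447 and 3198 at an unadjusted p under 0.05). In that fit the lone corn library is assumed to vary like the other groups.

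Whether the effect of diet differed between midgut sections was tested with both interaction contrasts together. The test passed 2 of 45390 transcripts, and 1766 had an unadjusted p under 0.05. With a replicate block 1 of these 2 still passed, and with a block within each diet, chosen after seeing the data, no transcript passed with edgeR (1939 at an unadjusted p under 0.05). Same-numbered libraries correlated above 0.1 in 3 of 3 pairs for green bean M1 with M2, green bean M1 with M3 and corn M2 with M3. TRINITY_DN15222_c0_g1_i5 had no count in green bean M1 and 5.1 ± 1.22 CPM in corn M1, while the diets lay at 5.67 ± 3.42 and 4.01 ± 0.398 CPM in M2 and at 5.3 ± 2.65 and 5.99 ± 1.17 in M3 (edgeR adjusted p = 0.008372). TRINITY_DN6362_c0_g1_i1 averaged 1.63 ± 0.428 CPM in green bean M1 and had no count in corn M1, while in M2 it stood at 15.9 ± 2.78 on green bean and 11.6 ± 3.32 on corn (edgeR adjusted p = 0.008372). Neither falls under the rule for named transcripts, and both were named after their values were seen. Leaving out 1 library gave 1 to 9, and 2 to 9 with the transcripts of the full fit. DESeq2 called 162.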

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

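The comparison with other splits of the libraries was planned before its result was seen. The count of transcripts whose diet effect differed between midgut sections, 2 of 45390, stands here because it comes from a direct test of a difference between groups. For TRINITY_DN15222_c0_g1_i5 the log2 difference between green bean and corn was higher by 10.55 in M2 and by 9.88 in M3 than in M1 in the edgeR model, and both transcripts had an adjusted p of 0.008372. These fitted values rest on groups at 0 and are no bounds. With a replicate block 1 of the 2 was still called, and with a block within each diet, chosen after seeing the data, 0 were called with edgeR (1939 at an unadjusted p under 0.05). Among 30 splits drawn from 4000, 5 gave at least 2 transcripts, the real one included, and the highest other gave 5, so chance is not excluded for this count. Technical and biological explanations were not weighed for these 2 transcripts, and no biological explanation was tested.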

How the results depend on the processing

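Fits with 1 library left out but the transcripts of the full fit, without corn replicate 1, without corn replicates 2 and 3, without replicate 1 of green bean M1 and M3, and with a replicate block within each diet were chosen after seeing the data, and the other alternatives were planned. Where corn replicates 2 and 3 were left out, the lone corn library is assumed to vary like the other groups. The planned fits with 1 library left out were filtered anew and tested more transcripts, as many as 60489 for 45390 in the midgut, so the library is not the only change in them. Except where a cause is given, the cause was not tested.

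For salivary glands against midgut, the total of 9238 calls stayed within 1.5-fold under every alternative fitted, from 7164 to 9957 with 1 library left out (7233 to 9323 with the transcripts of the full fit), and 9975 with the replicate block, which the correlations of same-numbered libraries there call for. Of these 9975, 8686 were among the 9238. The directions were less stable, since no filter on low counts gave 8333 higher and 4908 lower, against 4125 and 5113. Without corn replicates 2 and 3 there were no residual degrees of freedom and no test.

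For the midgut sections, DESeq2 called 4367 transcripts for M2 against M1 and 4336 for M3 against M2. Corn libraries alone gave 700 for M2 against M1, 186 for M3 against M2 and 1609 for M3 against M1. The corn table gave 674, 176 and 1650, and green bean alone 515, 783 and 2792. Leaving out corn replicates 2 and 3 gave 493, 542 and 1821. These fits use fewer libraries. Leaving out corn replicate 1 gave 1206 for M3 against M2. With 1 library left out the ranges were 1311 to 1867 for M2 against M1, 1102 to 1459 for M3 against M2 and 4262 to 5394 for M3 against M1. With the transcripts of the full fit they were 1614 to 2110, 1376 to 1818 and 4920 to 5665, all within 1.5-fold, so the larger falls came only where the filter changed too.

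The diet counts depended strongly on the settings. DESeq2 called 1954 in M1, 3673 in M2, 1280 in M3 and 650 in the glands. No filter gave 882, 814, 2362 and 980. The 6 libraries of the section alone gave 1 in M1, 0 in M2 and 3 in M3. Sums per Trinity gene gave 5 in M1, 115 in M2 and 15 in the glands. The replicate block gave 1 in M3. Leaving out corn replicate 1 gave 254 in M1, 1722 in M2 and 6 in M3, and with sums per gene 1043, 3830, 3 and, in the glands, 78. Of the 46 transcripts called in M1, 37 were among the 254, and all 27 of M2 were among the 1722. Leaving out corn replicates 2 and 3 kept 3 of the 46 among 31 calls in M1 and 1 of the 27 among 90 in M2, and TRINITY_DN36618_c0_g1_i1 went from a log2 fold change of -11.90 to -1.50. Leaving out corn replicates 2 and 3 gave 90 in M2 and 44 in M3, and with sums per gene 0 in M1, 1 in M2 and 1 in the glands. Leaving out replicate 1 of green bean M1 and M3 gave 46 in M2, and with sums per gene 27 in M1 and 225 in M2. With 1 library left out the ranges were 15 to 73 in M1, 0 to 162 in M2, 0 to 0 in M3 and 0 to 1 in the glands, and with the transcripts of the full fit 17 to 98, 0 to 415, 0 to 0 and 0 to 1.

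For the difference of the diet effect between sections, DESeq2 called 162 and no filter 379. The replicate block gave 1, the block within each diet 0, sums per gene 0, no replicate 1 of green bean M1 and M3 0, no corn replicate 1 13, and no corn replicates 2 and 3 61. With 1 library left out the range was 1 to 9, and 2 to 9 with the transcripts of the full fit.

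For the tissue-restricted transcripts, dropping the filter on low counts, which is here the level of 1 CPM in the definition, let in 251288 transcripts for 27436 and gave 28419 for salivary glands, 23123 for M1, 21686 for M2 and 35915 for M3, which are no longer restricted transcripts as defined. A tau of at least 0.9, which is stricter, gave 557 for M1, 102 for M2 and 251 for M3, and a pseudocount of 0.1 gave 576, 114 and 338. Corn replicate 1 alone gave 1690, 801 and 1343. Salivary glands held the largest number in the planned settings other than no filter, where M3 did.

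Over 707 pairs of a named result with an alternative fit, the 24 named results kept their direction in all and their call in 620. They were chosen for the largest folds without overlap, many with a side at 0. Refits to the same libraries could hardly reverse them, so the kept direction is no test. The 87 lost calls were 49 for diet in M2, 20 for diet in M1, 11 for M3 against M2 and 7 for M2 against M1. Whether same-numbered libraries pair across sections is mixed, with correlations from 0.0336 to 0.554. The block within each diet gave 2185 for M2 against M1, 1921 for M3 against M2 and 6113 for M3 against M1. Depth limits what a 0 can show to about 3 counts over a group. The alternatives for normalized values (other pseudocounts, quantile normalization) and those for gene lists were not run, since the tables hold counts and no list could be applied.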

Other observations

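The tests chosen only after the result was seen are all 4 on the number of transcripts detected, those on gland RNA and on diet for the set of green bean M3 replicate 1, and those on library batch and on other isoforms for the transcripts of one diet. The tests of depth and of a few transcripts were first made over all tissues pooled, where the ratios were 0.984 and 0.988, values that would have left both explanations standing. They were then remade within tissues, because tissues differ in the number detected. The test on other isoforms also replaced an earlier one, on sums per gene, after its result was seen, and its standard errors within tissues were chosen later still, after those over all tissues.

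Corn replicates 2 and 3 detected fewer transcripts than the other libraries of their tissue. Depth is argued against within tissues, since after thinning all libraries to one total, the lowest of the other libraries still stood 1.087 times above the highest of the pair in the tissue where they came closest. With the 100 transcripts of most counts left out before thinning, that ratio was 1.101, which argues against a few transcripts taking most of the counts. Diet as the whole cause is argued against by corn replicate 1, which detected more than every green bean library in 4 of 4 tissues. A separate library batch stays open. Corn replicate 1 lay nearer to green bean than to corn replicates 2 and 3 in 2 of 4 tissues (transcripts at 10 CPM or more), and the labels name no batch. Differences between the insects in the pools were not tested.

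A set of 742 transcripts in 585 Trinity genes held 5.95% of counts in green bean M3 replicate 1, 1.03% in green bean M1 replicate 1, 0.171% in green bean M2 replicate 1 and at most 0.0613% in any other library. The set was picked for this pattern. Gland RNA is argued against by its highest share in the 6 gland libraries, 0.0134%, libraries that had no part in choosing the set. That share lay in green bean gland replicate 1, against 0.00161% and 0.00202% in green bean gland replicates 2 and 3 and at most 0.000256% in corn glands. Replicate 1 thus had the largest share in each green bean tissue, in M3 by the choice of the set, and the cause was not tested. Green bean diet stays open, since the other green bean M3 libraries, with a highest share of 0.0427%, were used to choose the set and decide nothing. Carry-over of M3 tissue into M1 replicate 1 is argued against by 85 M3 transcripts, whose counts there were 1.09% of those in M3 replicate 1, as in M1 replicates 2 and 3 (0.863% and 1.11%), against 17.4% for the set. One foreign source in both libraries stays open. Of 216 members with at least 1000 counts, 80.6% had a ratio between these libraries within 2-fold of their median, barely above the 80% named beforehand, while 9 members were at 0 in M1 replicate 1. The same share was not computed for other transcripts, so it does not tell a foreign source from insect transcripts that vary together. No source was identified.

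There were 4 transcripts that stood in all 12 green bean libraries at more than 10 times their level in every corn library, TRINITY_DN870_c0_g1_i2, TRINITY_DN870_c0_g1_i3, TRINITY_DN6183_c1_g2_i4 and TRINITY_DN1811_c2_g1_i8, chosen after their values were seen. The 9 other splits of the 6 replicate numbers gave 0, and 10 splits are too few for a share under 0.05. A library batch stays open. The median of their highest level in corn replicate 1 was 0 CPM, but low levels in every corn library were part of the choice, so this value decides nothing. For RNA of the food in the gut lumen, the gland level, 35.4% of the midgut level at the median, decides nothing. On corn, other isoforms of TRINITY_DN870_c0_g1, TRINITY_DN6183_c1_g2 and TRINITY_DN1811_c2_g1 stood at 173.8 ± 72.4, 29.3 ± 27.2 and 10.4 ± 5.29 CPM (SD, n = 12). On green bean they stood at 175.4 ± 62.1, 27.4 ± 13.8 and 8.87 ± 3.8 CPM. Read after they were seen, these levels argue against food RNA, as far as each Trinity gene comes from one organism. Another isoform of the same gene on corn stays open too. As a share of the level of the 4 transcripts, the other isoforms on green bean changed by a fall of 12.5% for TRINITY_DN6183_c1_g2, of 42.6% for TRINITY_DN1811_c2_g1 and of -2.32% for TRINITY_DN870_c0_g1, where they rose. The standard errors were 59.8%, 23.1% and 26.6% within tissues, and 58%, 51.4% and 41.5% over all libraries, too large to tell. A strain difference between the insects of the diets was not tested.

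Other splits of the libraries were counted for each comparison. For salivary glands against midgut, 1 of 50 splits drawn from 220 gave as many calls as the real 9238, the real one itself, and the highest other gave 2789. For M2 against M1, M3 against M2 and M3 against M1, 1 of 30 splits drawn from 200 did so, the real one, with 2241, 1896 and 5918 calls against 21, 6 and 2 in the highest other. No other split drawn came near these 4 counts. The draws covered only part of the splits, and they ignored the replicate numbers. They also mixed tissues within a group, which widens the spread and lowers the calls. By themselves they therefore do not exclude chance. For diet there were 10 splits of 6 libraries, too few for a share under 0.05. The real split gave 46 in M1 and the highest other 10, and in M2 27 and 3. In M3 and in the glands the real split gave 0 with edgeR (3236 and 1575 at an unadjusted p under 0.05, and 1280 and 650 with DESeq2), the highest other gave 0, and 10 of 10 splits were as large.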
